A study of Mus musculus with 10 samples.

How the data were processed

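RNA-seq of cells sorted by FACS from the lung mesenchyme of adult mice was analysed in 10 libraries, 2 for each of 5 lineages. Cells of the groups Axin2:Pdgfra, Axin2, Pdgfra and Negative came from a mouse line that carries Axin2CreERT2, a tdT reporter and PdgfraEGFP. Cells of the Wnt2 group came from another line, with Wnt2CreERT2 and the R26REFYP reporter, so that line and lineage cannot be separated for that group. CreERT2 is a tamoxifen-inducible recombinase that marks the cells expressing its driver gene, and their descendants. Groups and replicate numbers were taken from the labels, which number the Negative libraries 0 and 2 and the others 1 and 2. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. In the Negative and Wnt2 groups Xist and Y-linked transcripts differed between the libraries, so there the spread was not only technical.

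Per the submitters' processing notes, STAR and limma were used with the mouse build mm9; the tool versions, the annotation, the read counter and the steps in which limma was used are not given in the sources used here. The deposited tables hold a single log2 value per gene for each library, and this scale was inferred from the values. All 10 tables hold the same 14854 Ensembl gene identifiers, share the highest value of 19.25 and have medians of 9.1 to 9.11. Their distributions are near-identical above the low values, as quantile normalization leaves them. In each library the lowest value is shared by 310 to 2728 genes, 2.1% to 18.4% of all, and the step from it to the next value is 0.16 to 2.89 log2 units. A gene at that value is described as listed at the lowest value. No fold is printed against a group in which both libraries are listed there. The tables hold no counts, so sequencing depth is unknown and no counting interval was computed. Because the lowest value differs between libraries, fold changes of low genes depend partly on it.

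The tests, the fitted samples, the 28 gene lists, the rule for named genes and the first set of alternatives given at the end were fixed before the data were examined; that plan provided for log-scale files as well as for counts. The level of the filter on low values was set after the distributions of values were seen and before any comparison was fitted. Genes with a log2 value of at least 6 in at least 2 libraries were kept, 14177 in all. Symbols were matched to 14720 of the 14854 identifiers, and 134 had none. All 10 libraries entered a single linear model with a mean for each group and no covariate, which leaves 5 residual degrees of freedom. limma 3.58.1 in R 4.3.3 was used (lmFit, then eBayes with trend and robust), two-sided, with Benjamini-Hochberg (BH) adjustment over genes within each comparison and a threshold of 0.05. Log2 differences are given with their standard error, and group levels as mean ± SD of 2 libraries. Genes with near-identical copies, such as the hemoglobin genes and Cwc22, are uncertain where the authors' counting could split reads between copies.

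An F-test asked which genes differed among any of the 5 lineages. The comparisons were Axin2:Pdgfra minus Axin2, Axin2:Pdgfra minus Pdgfra, Axin2 minus Negative, Pdgfra minus Negative, Wnt2 minus the mean of the other 4 groups, and the interaction, (Axin2:Pdgfra minus Axin2) minus (Pdgfra minus Negative). A gene counted as lineage-enriched when it was higher, at an adjusted p under 0.05, in each of the 4 pairwise tests of its group. Agreement between differences that share no library was given as Pearson's correlation across genes, which are not independent replicates, and as the overlap of calls beside the overlap of independent lists.

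The gene lists were canonical Wnt target genes, Wnt ligands and secreted Wnt modulators, FGF ligands, BMP ligands and antagonists, TGF-beta ligands with latency proteins and response genes, smooth muscle contractile genes, fibrillar collagens and collagen processing, elastic fibre and matricellular genes, alveolar (Col13a1) fibroblast and lipofibroblast genes, adventitial (Col14a1, Pi16) fibroblast genes, pericyte genes, endothelial genes, immune cell genes, epithelial genes, mesothelial genes, Schwann cell and neuronal genes, erythroid genes, the IL6 family and STAT3 pathway, the Hedgehog pathway, the Notch pathway, chemokines and cytokines of stromal cells, growth factors for epithelium and endothelium, retinoid metabolism, cell cycle genes, dissociation and immediate early genes, heat shock and unfolded protein response genes, interferon response genes, and Y-linked genes with Xist. Of these, 27 were tested per comparison with camera (limma) at a preset inter-gene correlation of 0.01, with BH adjustment over the 27 lists, and the Y-linked list was given per library. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted with adjustment over all genes and over the list alone.

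Named genes followed a fixed rule. Per comparison they were the 10 genes with the largest increase and the 10 with the largest decrease past the threshold, provided that both libraries of a group lay beyond both of the other (all 8 for Wnt2) and that the mean in the higher group was above the median of genes. To these came up to 4 members of each list with the smallest adjusted p past the threshold, the sort genes Axin2, Pdgfra and Wnt2, and up to 10 lineage-enriched genes per group. Genes named outside this rule are said to be chosen after their values were seen.

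The procedure was tested on simulated data for 14177 genes of which 200 were changed. At a log2 change of 4, the share recovered was 18.3% for Axin2:Pdgfra against Axin2 and for Axin2:Pdgfra against Pdgfra, 33.3% for Axin2 against Negative, 26.7% for Pdgfra against Negative, 8.3% for the interaction and 45% for Wnt2 against the other 4; at a change of 1 it was 0% in each. With no change simulated, 0 genes were called by limma in each of these comparisons. The simulated values were normal, with the same spread of a gene in every group and no lowest value shared by many genes. The real groups differed in spread (limma's array weights 0.58 for Negative and 2.18 for Wnt2), and many genes were at the lowest value. Neither the shares recovered nor the absence of calls therefore carries over directly to the real libraries.

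Alternatives fixed in advance were no filter, limma without trend or robust, fits on the compared groups alone, a threshold of 0.01, treat against a log2 fold change of 1, the replicate number as a block, the second index sequence of the library label as a block, and leaving out each library in turn; a group left with a single library is then assumed to vary like the others. Alternatives added after the data were seen were a filter at a log2 value of 8, raising every value under 6 to 6, limma's array weights, removal of a smooth trend on transcript length from each library, and leaving out 2 pairs of libraries: Negative 2 with Wnt2 2, and Negative 2 with Axin2:Pdgfra 2. Transcript lengths and chromosomes came from the GENCODE M21 annotation of another build than the authors', so no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Markers of alveolar type 1 and type 2 cells used in the closing observations were listed after the Negative-enriched genes had been seen.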

Results

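Cells of the lung mesenchyme of adult mice were sorted by FACS into 5 lineages, and RNA-seq was done on 2 libraries of each. The lineages were named after the labels they carried: Axin2 and Pdgfra together (Axin2:Pdgfra), Axin2 alone, Pdgfra alone, none of these (Negative), and Wnt2, the last from a separate mouse line. The comparisons below asked which transcripts went with each label, with attention to signals for the epithelium and to contractile and matrix genes of myofibroblasts. After low genes were set aside, 14177 were tested. The share of genes at the lowest value of the library ranged from 2.1% in Pdgfra library 2 to 18.4% in Negative library 2, with 15% in Axin2:Pdgfra library 2. Spearman correlations were 0.778 to 0.929 within groups (median 0.857, 5 pairs) and 0.671 to 0.885 between groups (median 0.784, 40 pairs), so the ranges overlapped. The first 3 principal components held 22.6%, 16.2% and 12.6% of the variance.

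Xist, the transcript of the inactive X chromosome, was between 16.68 and 17.72 (log2) in 8 libraries, 7.81 in Wnt2 library 2 and 8.57 in Negative library 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at 11.48, 10.85, 11.1 and 10.81 in Wnt2 library 2 and at 10.74, 9.73, 10.03 and 10.02 in Negative library 2. In Wnt2 library 1 they were at 8.15, 5.93, 7.61 and 5.08 beside Xist at 17.04. In the remaining 7 libraries Ddx3y, Eif2s3y, Kdm5d and Uty were at 3.36 or less. Sex was not modelled.

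Pdgfra, a receptor for platelet-derived growth factors and the gene that carries the EGFP reporter, was higher in each group with the Pdgfra label than in its partner. Its level was 15.06 ± 0.21 in Axin2:Pdgfra (log2, mean ± SD, n = 2 in each group), 13.25 ± 0.35 in Axin2, 14.78 ± 0.2 in Pdgfra, 12.67 ± 0.95 in Negative and 16.15 ± 0.14 in Wnt2. Pdgfra rose by 1.81 ± 0.36 (log2 ± SE; limma, BH-adjusted p = 0.0177; 95% interval 1.04 to 2.59) from Axin2 to Axin2:Pdgfra and by 2.11 ± 0.36 (adjusted p = 0.00587; 1.33 to 2.88) from Negative to Pdgfra. The first of these calls ended without Axin2:Pdgfra library 1 (adjusted p = 0.0596), Axin2:Pdgfra library 2 (0.145), Axin2 library 1 (0.0585) or Axin2 library 2 (0.201). The call against Negative ended without Pdgfra library 1 (0.0573) or Pdgfra library 2 (0.0818). Against the mean of the other 4 groups, Pdgfra was higher in Wnt2 by 2.21 ± 0.29 (adjusted p = 0.00105; 1.6 to 2.82), a call held whichever library was left out.

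Axin2, a target of canonical Wnt signalling, did not pass the threshold with the Axin2 label. It was 10.79 ± 1.77 in Axin2:Pdgfra, 11.02 ± 0.78 in Axin2, 10.73 ± 0.47 in Pdgfra, 10.37 ± 0.41 in Negative and 11.33 ± 0.06 in Wnt2 (mean ± SD, n = 2). The difference of Axin2:Pdgfra from Pdgfra was 0.07 ± 0.74 (adjusted p = 0.982; 95% interval -1.53 to 1.66), and that of Axin2 from Negative 0.65 ± 0.74 (adjusted p = 0.754; -0.94 to 2.25). The ligand Wnt2 was at 10.36 ± 0.65, 10.06 ± 0.48, 9 ± 1.87, 9.42 ± 0.75 and 9.86 ± 0.26 in the same order. In the Wnt2 group it differed from the other 4 by 0.15 ± 0.71 (adjusted p = 0.946; -1.38 to 1.68).

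**Figure D1:**
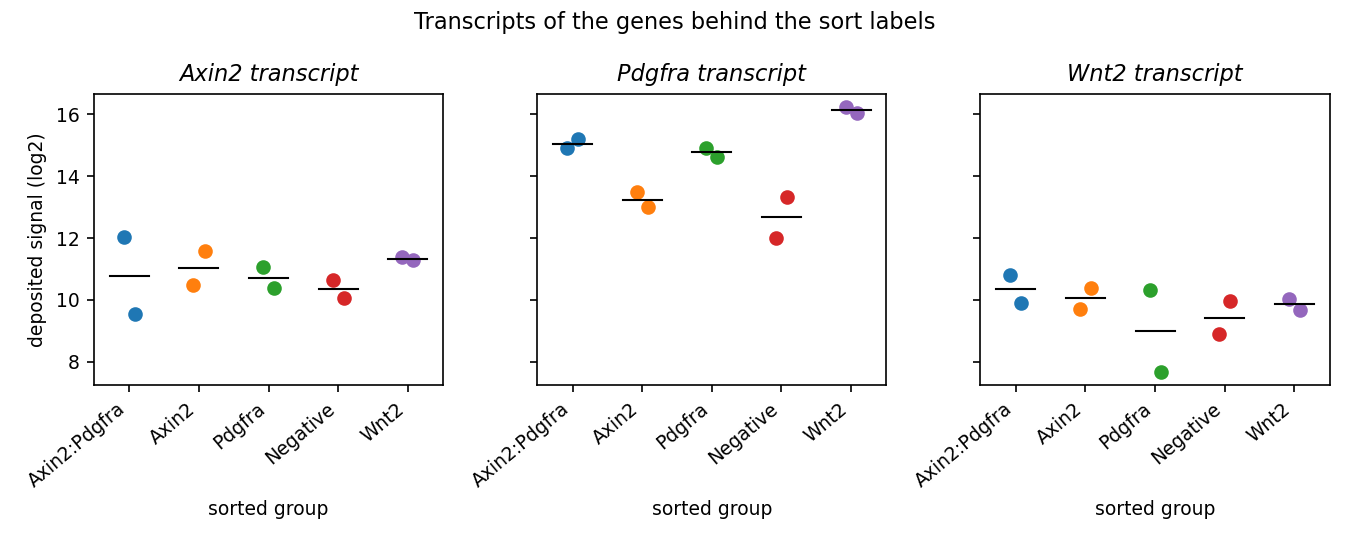
Levels of the Axin2, Pdgfra and Wnt2 transcripts in the 5 lineages (log2). Points are libraries, 2 per group, and bars are group means.

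Across the 5 lineages 1163 genes differed (limma F-test, adjusted p < 0.05; 3395 at unadjusted p < 0.05). Of these, 288 were highest in Negative, 251 in Axin2, 239 in Wnt2, 222 in Axin2:Pdgfra and 163 in Pdgfra. The count fell to 695 without Axin2 library 1, 592 without Axin2 library 2, 658 without Pdgfra library 1, 593 without Wnt2 library 1 and 634 without Wnt2 library 2. Between pairs of lineages, the largest counts were 953 for Axin2:Pdgfra and Negative, 824 for Negative and Wnt2 and 574 for Axin2 and Wnt2. The smallest were 6 for Axin2:Pdgfra and Pdgfra, 52 for Pdgfra and Wnt2, 85 for Axin2 and Negative and 90 for Axin2:Pdgfra and Wnt2, beside 320 for Axin2 and Pdgfra.

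Negative cells held 23 of the 26 genes that were higher in a lineage than in each of the others. Among the 10 with the largest margins were Hba-a1 and Hbb-bs, hemoglobin genes with near-identical copies, higher by 6.18 ± 1.29 (adjusted p = 0.0191) and 5.16 ± 1.14 (0.0275) than in the next group. Col4a3 and Lama3, components of epithelial basement membrane, were higher by 3.69 ± 0.51 (0.00863) and 3.37 ± 0.5 (0.0135). The others were Myh14, Rab11fip1, Sema3e, Lmo7, Cyp2b10 and Sec14l3, with margins of 2.85 to 3.94. Axin2 cells had 1 such gene, the actin cross-linker Flna (1.25 ± 0.25, adjusted p = 0.017). Pdgfra cells had the nuclear long noncoding RNA Neat1 (1.67 ± 0.28, 0.0091). Wnt2 cells had the cytoskeletal linker Macf1 (1.27 ± 0.18, 0.00592). Axin2:Pdgfra cells had 0 (limma; 41 at unadjusted p < 0.05). Macf1 lay near the top of the scale, where near-identical distributions tie a value to the rank of the gene. Its margin and standard error, here and below, therefore depend partly on the gaps between the top values.

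The set of 23 genes of Negative cells shrank to 13 without Axin2 library 1, 0 without Axin2 library 2 (limma; 143 at unadjusted p < 0.05), 8 without Pdgfra library 1, 4 without Pdgfra library 2, 15 without Negative library 0, 3 without Negative library 2, 14 without Wnt2 library 1 and 15 without Wnt2 library 2. Flna was lost without Axin2 library 1, Axin2 library 2, Negative library 2 or Axin2:Pdgfra library 1 (another gene passed in the last of these), and the count for Axin2 was 18 without Negative library 0. Neat1 was lost without Pdgfra library 1, Pdgfra library 2 or Wnt2 library 2, and when a trend on transcript length was removed. Macf1 was lost without Axin2:Pdgfra library 2, Pdgfra library 1, Pdgfra library 2 or Wnt2 library 1. The count for Wnt2 was 4 without Negative library 0, 3 without Negative library 2 and 2 without Axin2:Pdgfra library 1.

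**Figure D2:**
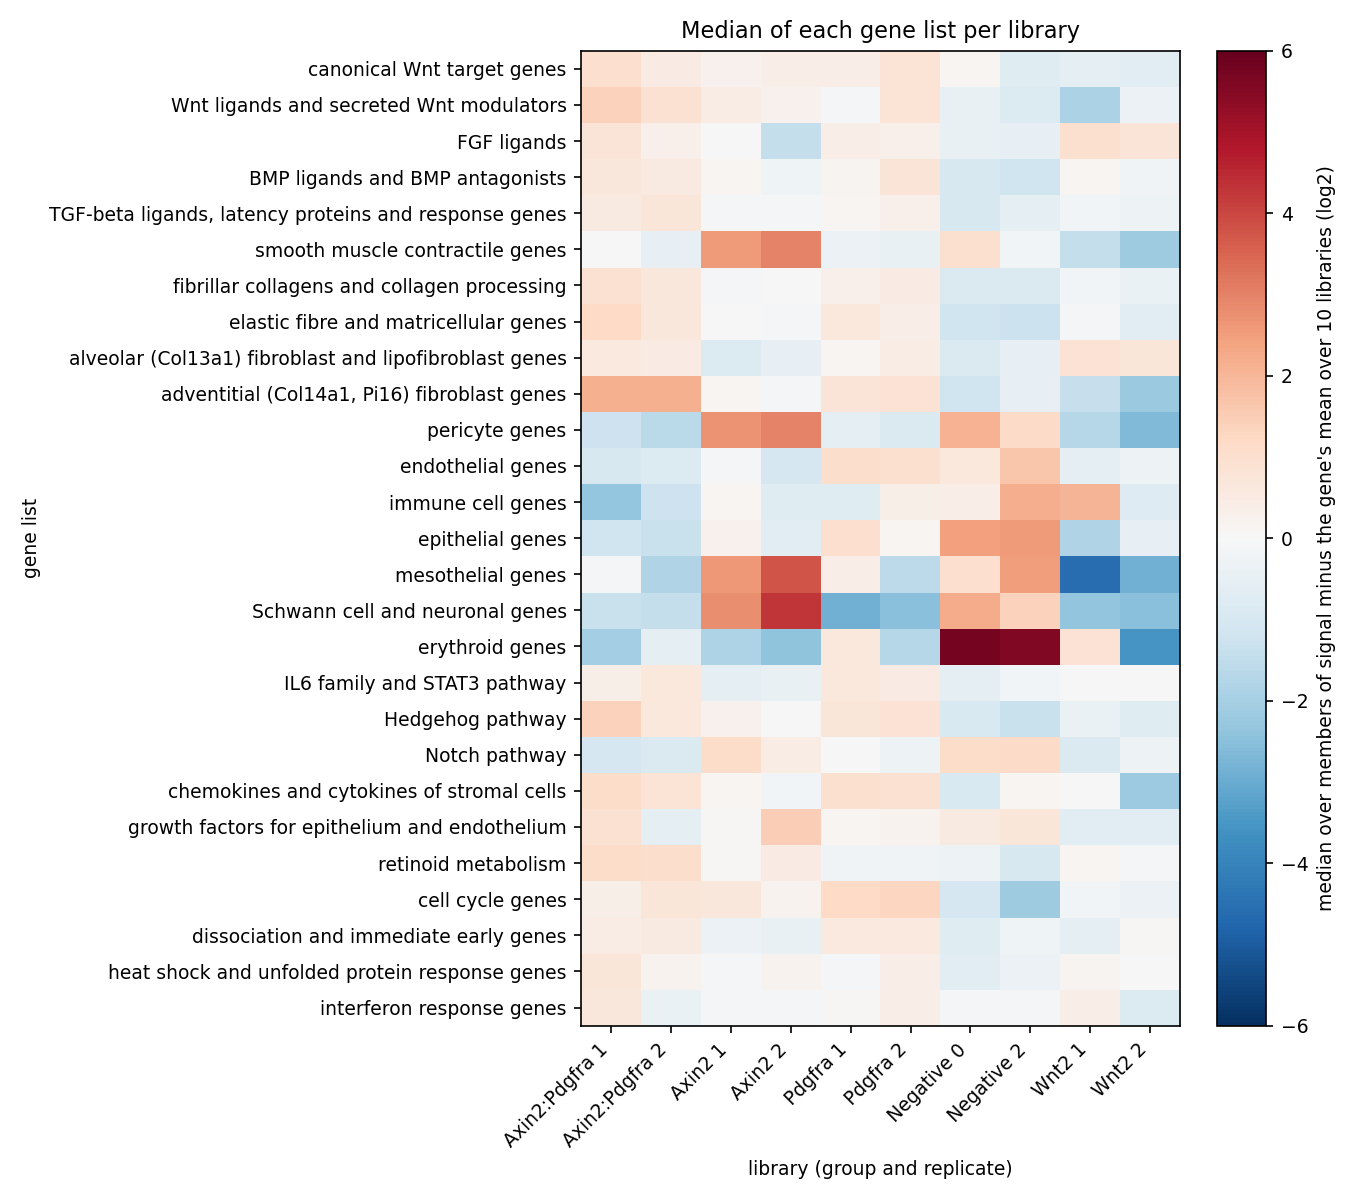
Median over the genes of each of 27 lists in each library (log2 signal minus the mean of the gene over 10 libraries). Libraries are ordered by group, 2 per group.

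Among cells with the Axin2 label, those that also carried Pdgfra had less of the transcripts of mural cells, the pericytes and smooth muscle around vessels. Pdgfrb, the growth factor receptor of pericytes, fell from 16.63 ± 0.44 in Axin2 to 12.64 ± 0.04 in Axin2:Pdgfra (mean ± SD, n = 2 in each), a difference of -3.99 ± 0.31 (log2 ± SE; limma, adjusted p = 1.69e-05). Rgs4, a regulator of G-protein signalling, fell by -9.59 ± 0.95 (0.000119), the largest decrease. Postn, a matricellular protein of myofibroblasts, fell by -5.58 ± 0.4 (1.69e-05). Of 16 pericyte genes 12 fell and 0 rose (13 and 0 adjusted over the list alone), with Pdzd2 at -3.82 ± 0.3 (1.69e-05) and Gucy1a1 at -4.12 ± 0.39 (0.000115). The pericyte median was -4.36 (camera, adjusted p = 2.93e-22; adjusted p = 0.0627 with an estimated correlation). Of 16 smooth muscle genes 5 fell (13 adjusted over the list alone), among them Acta2, smooth muscle actin, by -3.54 ± 0.66 (0.0114), and Myh11, its myosin, by -3.81 ± 0.77 (0.0186). The smooth muscle median was -2.55 (camera, adjusted p = 1.34e-13; adjusted p = 0.0636 with an estimated correlation).

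Fibroblast transcripts were higher in Axin2:Pdgfra than in Axin2 cells. Lum, a collagen-binding proteoglycan, rose by 7.62 ± 1.19 (limma, adjusted p = 0.00411), and Dcn, another, by 2.86 ± 0.54 (0.0123). Of 19 adventitial fibroblast genes 6 rose (11 adjusted over the list alone; median 1.61), with Mfap5 at 2.42 ± 0.49 (0.02) and C3 at 1.03 ± 0.22 (0.0272). Of 19 alveolar fibroblast genes 3 rose (12 adjusted over the list alone, median 0.78). They were Macf1 by 2.1 ± 0.18 (3.41e-05), Itga8, an integrin, by 1.43 ± 0.26 (0.00977), and Slc27a6 by 5.51 ± 1.3 (0.042). The call of Slc27a6 ended in most fits with a library left out, where its rise ranged from 4.61 to 6.4. Of 19 elastic fibre and matricellular genes 6 rose, fibronectin Fn1 by 1.39 ± 0.23 (0.00629) among them, and only Postn fell (12 and 2 adjusted over the list alone; median 1.33). Among 19 collagen genes Lox, which cross-links collagen, rose by 2.35 ± 0.43 (0.00977; 7 genes adjusted over the list alone; median 0.76). Camera gave adjusted p of 1.83e-10 for the adventitial list, 3.68e-10 for the alveolar, 5.43e-06 for the elastic fibre and 2.24e-06 for the collagen list (adjusted p = 0.0636, 0.0627, 0.076 and 0.076 with an estimated correlation).

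Signalling genes differed as well. Il6, a cytokine, was at 9.94 ± 0.07 in Axin2:Pdgfra and 2.55 ± 1.14 in Axin2 (7.39 ± 1.53, limma, adjusted p = 0.0226), where 1 of the 2 libraries was at the lowest value. Its relatives Osmr (2.48 ± 0.35, 0.00203) and Il6ra (3.36 ± 0.78, 0.039) rose, and Jak2 fell by -2.32 ± 0.52 (0.0327). Among 14 IL6 pathway genes the calls were thus 3 up and 1 down (5 and 1 adjusted over the list alone, median 0.99). With a library left out, the call of Osmr held, those of Il6ra and Jak2 ended in most fits and that of Il6 in some. The differences then ranged from 2.39 to 4.34 for Il6ra, -2.44 to -2.21 for Jak2 and 6.58 to 8.2 for Il6. Hhip, which binds Hedgehog ligands, rose by 4.81 ± 0.73 (0.00342), alone among 11 Hedgehog genes (2 adjusted over the list alone; median 1.02). Notch3, Nrarp and Hey1 fell by -5.61 ± 0.55 (0.000119), -5.46 ± 1.01 (0.0112) and -4.04 ± 0.84 (0.0233) among 14 Notch genes (5 adjusted over the list alone; median -1.68). Of 18 TGF-beta genes Ltbp1 rose by 1.26 ± 0.3 (0.0436) and Ltbp2 fell by -3.47 ± 0.45 (0.0012). Adjusted over the list alone, 11 and 2 passed (median 0.81). The call of Ltbp1 ended in most fits with a library left out, where its rise ranged from 1.11 to 1.41. Adjusted p by camera was 0.00112 for IL6, 0.00977 for Hedgehog, 5.95e-07 for Notch and 0.000397 for TGF-beta genes (adjusted p = 0.0636, 0.076, 0.0627 and 0.0627 with an estimated correlation). The Hedgehog call ended without Axin2:Pdgfra library 1 (adjusted p = 0.0803).

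Markers of other cell types and of tissue handling also moved. Among 21 dissociation and immediate early genes 5 rose and 0 fell in Axin2:Pdgfra (10 and 0 adjusted over the list alone; median 0.91), such as Zfp36 by 1.56 ± 0.24 (limma, adjusted p = 0.004) and Egr1 by 1.08 ± 0.19 (0.00919). Mesothelial Upk3b and Gpm6a fell by -7.87 ± 1.76 (0.0334) and -6.09 ± 1.35 (0.032), 2 of 9 genes (1 up and 4 down adjusted over the list alone; median -3.73); 1 Axin2:Pdgfra library was at the lowest value for Gpm6a. Endothelial Eng and Esam fell by -2.22 ± 0.36 (0.00533) and -3.15 ± 0.76 (0.0471), 2 of 15 genes in either adjustment (median -0.71). None of 7 Schwann cell or 18 epithelial genes passed over all genes (3 Schwann cell genes fell adjusted over the list alone; medians -3.68 and -0.63). These lists had camera adjusted p of 6.07e-09 (dissociation), 0.00158 (mesothelial), 0.00414 (endothelial), 0.000385 (Schwann cell) and 0.00704 (epithelial), and adjusted p = 0.073 to 0.398 with an estimated correlation. Without Axin2 library 1 the endothelial (adjusted p = 0.159) and epithelial (0.331) calls ended.

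The remaining 12 lists did not pass in Axin2:Pdgfra against Axin2, though Lgr5, a Wnt target and receptor with 1 of the 2 Axin2 libraries at the lowest value, rose by 7.89 ± 1.78 (limma, adjusted p = 0.0342) among canonical Wnt targets and Bmper by 2.52 ± 0.53 (0.0246) among BMP genes. Of the growth factors Vegfd rose by 1.76 ± 0.35 (0.0159), while Pdgfa and Hbegf fell by -4.32 ± 0.68 (0.00422) and -5.35 ± 0.91 (0.00653). Medians were 0.14 for canonical Wnt targets, 1.39 for Wnt ligands, 0.01 for FGF ligands, 0.22 for BMP, -0.76 for immune cell, 1.12 for erythroid, 0.63 for chemokine, -0.43 for growth factor, 0.3 for retinoid, -0.23 for cell cycle, 0.39 for heat shock and 0.36 for interferon response genes (camera, adjusted p = 0.0515 to 0.786).

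In this comparison 326 genes passed (131 higher and 195 lower in Axin2:Pdgfra; 2004 at unadjusted p < 0.05). The opioid precursor Penk, at 10.36 ± 0.47, and Lsamp, at 9.16 ± 0.68, were among the higher genes and were listed at the lowest value in both Axin2 libraries. The 326 fell to 145 without Axin2:Pdgfra library 2, 99 without Axin2 library 1, 35 without Axin2 library 2 and 217 without Pdgfra library 1. The 131 higher and 195 lower genes became 47 and 188 without Axin2:Pdgfra library 1, 30 and 115 without Axin2:Pdgfra library 2, 53 and 46 without Axin2 library 1, 224 and 231 without Negative library 0, and 233 and 240 without Negative library 2. Of 60 named genes past the threshold, 10 held in all 10 such fits: Rgs4, Actc1, Clstn2, Postn, Macf1, Pdgfrb, Pdzd2, Gucy1a1, Notch3 and Osmr. The calls that ended numbered 27 and 35 without Axin2:Pdgfra library 1 or 2, 38 and 48 without Axin2 library 1 or 2, 10 and 11 without Pdgfra library 1 or 2, and 10 and 12 without Wnt2 library 1 or 2. Their adjusted p reached 0.293.

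Cells with Pdgfra alone had more matrix transcripts than Negative cells. The Negative libraries held the most epithelial (library medians 2.45 and 2.55) and erythroid transcripts (5.72 and 5.57). A smaller share of fibroblasts in Negative was therefore not told apart from lower expression in its fibroblasts. Lum rose by 9.55 ± 1.19 (log2 ± SE; limma, adjusted p = 0.00101), from 3.26 ± 0.83 in Negative, with 1 library at the lowest value, to 12.8 ± 1.58 in Pdgfra (mean ± SD, n = 2 in each). The fibrillar collagens Col1a1, Col1a2 and Col3a1 rose by 1.99 ± 0.33 (0.00495), 2.03 ± 0.27 (0.00137) and 2.27 ± 0.38 (0.00543), among 6 of 19 collagen genes (13 adjusted over the list alone; median 1.32). Of 19 elastic fibre and matricellular genes 10 rose and 1 fell (12 and 1 adjusted over the list alone; median 2.09), Fbln1 rising by 2.8 ± 0.36 (0.00107) and Postn falling by -2.76 ± 0.4 (0.00273). Of 19 adventitial genes 7 rose (12 adjusted over the list alone; median 1.46), with Dcn at 3.54 ± 0.54 (0.00342) and Col14a1 at 3.36 ± 0.56 (0.00536). Of 19 alveolar fibroblast genes 4 rose (7 adjusted over the list alone; median 0.72), with Itga8 at 2.48 ± 0.26 (0.000407) and Tcf21, a transcription factor, at 2.05 ± 0.48 (0.0352). Camera gave adjusted p of 3.92e-07, 2.18e-08, 2.13e-09 and 9.97e-07 for these lists in turn, and adjusted p = 0.0706 to 0.0732 with an estimated correlation.

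Ligands and pathway genes followed in Pdgfra against Negative cells. Bmp3 rose by 3.22 ± 0.41 (limma, adjusted p = 0.00101), and the list of BMP genes had a median of 1.03. Of 18 TGF-beta genes 5 rose, such as Thbs1 by 2.87 ± 0.28 (0.000295), and Ltbp2 fell by -2.7 ± 0.45 (0.00495; 9 and 1 adjusted over the list alone; median 0.76). Of 11 Hedgehog genes 3 rose (4 adjusted over the list alone; median 1.83): Hhip by 4.33 ± 0.73 (0.0055), Boc by 2.9 ± 0.66 (0.0327), and Gli1, which was listed at the lowest value in both Negative libraries. Osmr and Il6 rose by 2.44 ± 0.35 (0.00205) and 6.89 ± 1.53 (0.0284), 2 of 14 IL6 pathway genes in either adjustment (median 0.75), with 1 Negative library at the lowest value for Il6. Csf1 and Cxcl1 rose by 2.93 ± 0.58 (0.0147) and 2.34 ± 0.5 (0.0228) among 16 chemokine genes (3 adjusted over the list alone; median 0.75). By camera, adjusted p was 0.000508 for BMP, 9.68e-05 for TGF-beta, 5.65e-05 for Hedgehog, 0.00139 for IL6 and 0.0379 for chemokine genes, and adjusted p = 0.0706 to 0.308 with an estimated correlation. The chemokine call ended without Pdgfra library 2 (adjusted p = 0.127) or Negative library 0 (0.361).

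Pericyte transcripts were lower in Pdgfra than in Negative cells, with 6 of 16 genes falling (2 up and 11 down adjusted over the list alone; median -2.54). Pdgfrb fell by -2.7 ± 0.31 (limma, adjusted p = 0.000546) and Notch3 by -3.59 ± 0.55 (0.0036), the latter alone among 14 Notch genes in either adjustment (median -0.89). Of 5 erythroid genes 3 fell (5 adjusted over the list alone; median -6.18), Hba-a1 by -6.18 ± 1.29 (0.0191), with its near-identical copies. Ager and Cldn18, markers of alveolar type 1 cells, fell by -3.06 ± 0.47 (0.00344) and -2.34 ± 0.43 (0.0091), 2 of 18 epithelial genes (7 adjusted over the list alone; median -1.89). Mesothelial Krt19 fell by -3.99 ± 0.86 (0.0233), 1 of 9 (3 adjusted over the list alone; median -2.76). Schwann cell Kcna1, at the lowest value in 1 Pdgfra library, fell by -8.35 ± 1.73 (0.0189) and Sox10 was listed at the lowest value in both Pdgfra libraries, 2 of 7 genes (5 adjusted over the list alone, median -3.75). The call of Sox10 ended in most fits with a library left out. None of 19 immune cell genes passed in either adjustment (median -1.56). The camera test gave adjusted p of 3.97e-08 for pericyte, 0.00117 for Notch, 4.17e-06 for erythroid, 3.62e-05 for epithelial, 0.0201 for mesothelial, 5.65e-05 for Schwann cell and 0.0111 for immune cell genes, and adjusted p = 0.0706 to 0.402 with an estimated correlation. The mesothelial call ended without Pdgfra library 2 (adjusted p = 0.272) or Negative library 2 (0.106), and the immune call without Negative library 2 (0.385).

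Immediate early genes were higher in Pdgfra than in Negative cells, 6 of 21 (13 adjusted over the list alone; median 1.23). Nr4a1 rose by 2.4 ± 0.29 (limma, adjusted p = 0.000863), Fosb by 2.15 ± 0.33 (0.00342) and Egr1 by 1.41 ± 0.19 (0.00161). None of 13 heat shock or 14 cell cycle genes passed in either adjustment (medians 0.53 and 1.98). Camera gave adjusted p of 4.1e-09, 0.0111 and 0.0396 for the 3 lists, and adjusted p = 0.0743, 0.217 and 0.128 with an estimated correlation. The heat shock call ended without Pdgfra library 2 (adjusted p = 0.137) or Negative library 0 (0.0967), and the cell cycle call without Pdgfra library 1 (0.0572), Pdgfra library 2 (0.0866), Negative library 0 (0.0979) or Negative library 2 (0.105). Among the 8 lists that did not pass, Mylk rose by 1.37 ± 0.21 (0.00376) in the smooth muscle list and Vegfd by 2.67 ± 0.35 (0.00107) in the growth factor list. Their medians were 0.39 for canonical Wnt targets, 0.71 for Wnt ligands, 0.62 for FGF ligands, -1.13 for smooth muscle, -0.14 for endothelial, -0.39 for growth factor, 0.29 for retinoid and 0.8 for interferon response genes (camera, adjusted p = 0.0542 to 0.948). The growth factor list had a mean of -0.24 and a test direction of up.

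Between Pdgfra and Negative cells 412 genes passed (limma; 288 higher and 124 lower in Pdgfra; 2497 at unadjusted p < 0.05). Fam163b and Pappa2, at 12.67 ± 0.46 and 11.18 ± 0.81 in Pdgfra (mean ± SD, n = 2), were listed at the lowest value in both Negative libraries. Wnt7a, at the lowest value in 1 Pdgfra library, fell by -8.29 ± 1.99 (adjusted p = 0.0398). Wnt10b, at 9.09 ± 0.45 in Negative, was listed at the lowest value in both Pdgfra libraries. The calls of Wnt7a and Wnt10b ended in most fits with a library left out. The 412 changed to 86 without Pdgfra library 1, 82 without Pdgfra library 2, 633 without Negative library 0, 262 without Wnt2 library 1 and 267 without Wnt2 library 2. The excess of higher genes was not kept without Pdgfra library 2 (42 higher and 40 lower) or with only these 2 groups fitted (149 and 150), and was larger without Negative library 0 (554 and 79). Of 64 named genes past the threshold 14 held in all 10 fits, Lum, Bmp3, Thbs1, Col1a2, Fbln1, Postn, Itga8, Macf1, Pdgfrb and Egr1 among them. The calls that ended numbered 39 and 45 without Pdgfra library 1 or 2, 21 and 20 without Negative library 0 or 2, 10 without either Axin2 library, and 15 and 13 without Wnt2 library 1 or 2, with adjusted p up to 0.255.

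Many of the same genes moved with the Pdgfra label whether or not the Axin2 label was present. Lum, Dcn, Itga8, Macf1, Osmr, Il6, Hhip and Vegfd rose in both comparisons, and Pdgfrb, Notch3, Postn, Ltbp2, Pdzd2 and Gucy1a1 fell in both. In all, 68 genes rose in both and 45 fell in both, beside 2.66 and 1.71 from independent lists of these sizes, and 0 moved in opposite directions. Of the 326 genes of the first comparison 92.9% had the same sign in the second, and of the 412 genes of the second 90.8% had the same sign in the first. The differences correlated at r = 0.29 across 14177 genes, which are not independent replicates, and the 2 comparisons shared no library.

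The interaction of the labels gave 0 genes (limma; 1296 at unadjusted p < 0.05; smallest adjusted p 0.237). It gave 42 without Negative library 0. Chosen from these after their values were seen, Myh11 differed by -5.02 and Postn by -3.45 (limma, adjusted p = 0.0287 each) and Mylk by -1.74 (0.0422), and all but Plpp1 (3.68) were negative. By camera 3 of 27 lists passed. The fall of pericyte genes with Pdgfra was larger among Axin2-labelled cells by a median of -2.05 (adjusted p = 1.42e-08), and that of smooth muscle genes by -1.68 (1.43e-06). Erythroid genes differed by 7.59 (camera, adjusted p = 1.14e-06), with medians of 1.12 among cells with the Axin2 label and -6.18 among those without. They were high in the Negative libraries alone (library medians 5.72 and 5.57). The Negative group, which also held the most epithelial transcripts, enters the pericyte and smooth muscle interactions as well. Each of the 3 lists had adjusted p = 0.483 by camera with an estimated correlation. Adjusted over the list alone, 8 of 16 pericyte, 3 of 16 smooth muscle and all 5 erythroid genes passed. The other 24 lists had camera adjusted p of 0.11 to 0.939. Median, mean and test direction differed in sign for FGF ligands (1.06, -0.78, up), adventitial (0.07, -0.18, down), IL6 (0.13, -0.07, up) and chemokine genes (-0.82, 0.01, down).

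**Figure D3:**
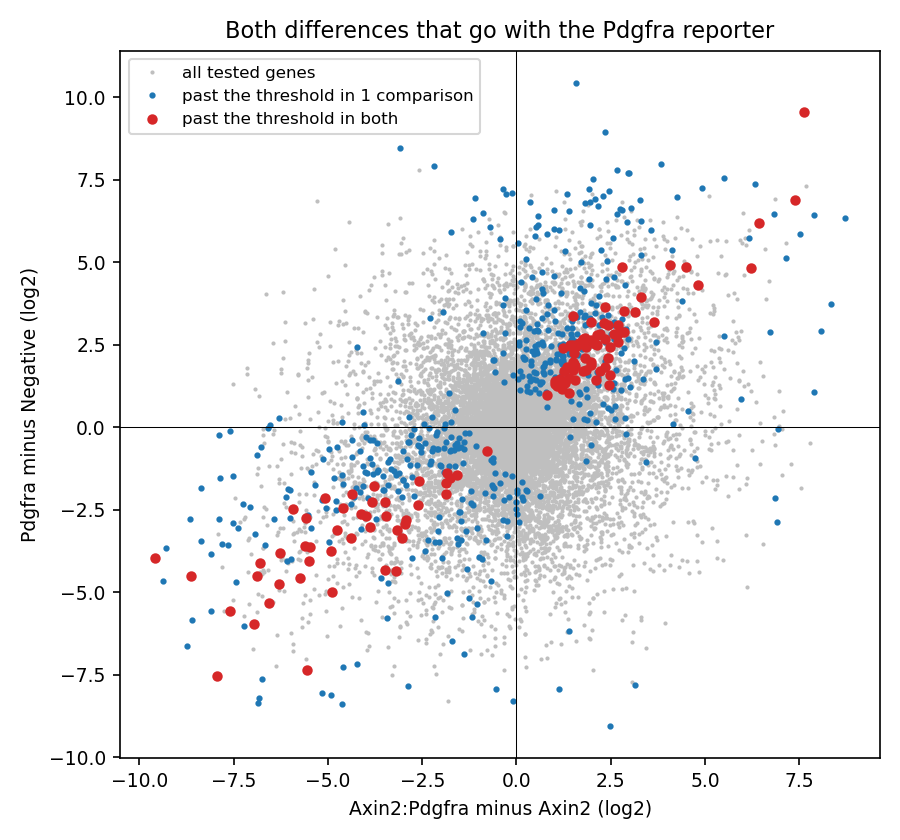
Difference of Axin2:Pdgfra from Axin2 against that of Pdgfra from Negative for each tested gene (log2, 2 libraries per group). Blue points passed in 1 comparison and red points in both.

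Few genes passed the threshold between Axin2:Pdgfra and Pdgfra cells. With 2 libraries per group this does not show that the cells were alike. Neat1 fell from 16.36 ± 0.31 in Pdgfra to 13.58 ± 0.26 in Axin2:Pdgfra (mean ± SD, n = 2 in each), by -2.78 ± 0.28 (log2 ± SE; limma, adjusted p = 0.00131). Il18r1, a cytokine receptor chain, fell by -5.56 ± 0.66 (0.00495), and Epas1, a hypoxia-responsive transcription factor, by -2.52 ± 0.31 (0.00519). Sema6d (-3.27 ± 0.45, 0.0139), Pcdh1 (-2.4 ± 0.36, 0.0263) and Akap5 (-3.52 ± 0.56, 0.0409) completed the 6 genes that passed, and 0 rose (limma, 1801 of either sign at unadjusted p < 0.05). Akap5 was also enriched in Negative cells (15.54) and is among the alveolar type 1 markers of the closing observations. It was at 14.13 and 12.23 in Pdgfra libraries 1 and 2 and at 9.85 and 9.48 in Axin2:Pdgfra. Its fall was not told apart from a difference in epithelial RNA. Endothelial genes also had lower library medians in Axin2:Pdgfra (-0.98 and -0.84) than in Pdgfra (1.06 and 0.95). Whether the falls of the other genes came from RNA of such cells was not tested. All 6 calls ended without Pdgfra library 1, where the count was 0 (923 at unadjusted p < 0.05; adjusted p up to 0.658). The count was 49 without Axin2:Pdgfra library 1, 12 without Axin2:Pdgfra library 2, 11 without Pdgfra library 2, 57 without Negative library 0 and 51 without Negative library 2. Genes then rose as well in some fits, 6 of the 11 without Pdgfra library 2, 4 of the 57 and 3 of the 51. With a trend on transcript length removed, the calls of Akap5 and Pcdh1 ended (adjusted p = 0.0545 each) and the difference of Neat1 was -1.86. Without Axin2:Pdgfra library 2, 2 of the 6 calls ended (adjusted p up to 0.12), and 1 ended without each of Pdgfra library 2 (0.122), Axin2 library 1 (0.0621), Axin2 library 2 (0.0693), Wnt2 library 1 (0.0605) and Wnt2 library 2 (0.0616).

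No member of the 27 lists passed over all genes in this comparison (limma). Adjusted over the list alone, 9 of 15 endothelial and 9 of 18 epithelial genes fell in Axin2:Pdgfra against Pdgfra, with medians of -1.89 and -1.93 (camera, adjusted p = 1.79e-10 and 1.56e-08; adjusted p = 0.317 for each with an estimated correlation). Adventitial genes had a median of 1.01 (4 up and 1 down adjusted over the list alone; camera, adjusted p = 0.000245; adjusted p = 0.33 with an estimated correlation). Medians were 1.02 for Wnt ligands, 1.44 for retinoid genes (1 rose adjusted over the list alone), 0.34 for TGF-beta, 0.24 for collagen and 0.45 for elastic fibre genes (1 fell), and -0.6 for pericyte (4 fell), -1.06 for immune cell (1 fell) and -1.01 for Notch genes (1 fell). For these 8 lists camera gave adjusted p of 0.0239 to 0.0416, and adjusted p = 0.317 to 0.625 with an estimated correlation. Only the endothelial and epithelial calls held in all 10 fits; 9 of the 11 calls ended without Axin2:Pdgfra library 1, 3 without Axin2:Pdgfra library 2, 8 without Pdgfra library 1, 5 without Pdgfra library 2, and the Notch call without Negative library 0 (adjusted p = 0.062) or Negative library 2 (0.0655). The highest adjusted p was 0.523, for collagen genes without Pdgfra library 1.

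The other 16 lists did not pass (camera, adjusted p = 0.0994 to 0.933), with medians from -0.91 for cell cycle genes to 0.77 for Schwann cell genes. They included canonical Wnt targets (median 0.17, mean 0.21, test direction down), FGF ligands (0.31, -0.23, down), mesothelial (0.43, -0.43, down), IL6 (0.12, -0.06, up) and growth factor genes (0.16, -0.11, down), in which the signs differed. BMP genes had a median of 0.31, smooth muscle 0.45, alveolar fibroblast 0.34, erythroid -0.8, Hedgehog 0.39, chemokine 0.18, dissociation -0.25, heat shock 0.13 and interferon response genes -0.25.

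Cells with the Axin2 label alone differed from Negative cells in matrix and blood transcripts, in calls that mostly depended on single libraries. Because the Negative libraries held the most epithelial and erythroid transcripts, higher matrix levels were not told apart from a larger share of fibroblasts. Col5a1 rose by 2.06 ± 0.4 (log2 ± SE; limma, adjusted p = 0.0432), Col6a2 by 1.46 ± 0.28 (0.0396) and Col1a2 by 1.31 ± 0.27 (0.0488), 3 of 19 collagen genes (7 up and 2 down adjusted over the list alone; median 0.85). Tlr4, a receptor for bacterial lipopolysaccharide, was at 10.55 ± 0.29 in Axin2 and 3.49 ± 1.17 in Negative (mean ± SD, n = 2 in each), where 1 library was at the lowest value (7.06 ± 1.07, 0.0135). Fbln1 and Bgn rose by 1.83 ± 0.36 (0.0437) and 0.91 ± 0.18 (0.0437), 2 of 19 elastic fibre genes (8 adjusted over the list alone; median 1.08). C3 and Col14a1 rose by 1.22 ± 0.22 (0.0271) and 2.76 ± 0.56 (0.0452), 2 of 19 adventitial genes (5 up and 1 down adjusted over the list alone; median 0.95). Thbs1 rose by 1.61 ± 0.28 (0.0217), 1 of 18 TGF-beta genes (6 adjusted over the list alone; median 0.73). Of the 10 fits with a library left out, Col5a1 passed in 2, Col6a2 in 5, Col1a2 in 0, Fbln1 and Bgn in 1, C3 in 5, Col14a1 in 3, Thbs1 in 7 and Tlr4 in 8. These lists had camera adjusted p of 0.000648 for collagen, 5.08e-07 for elastic fibre, 3.78e-05 for adventitial and 0.000643 for TGF-beta genes, and adjusted p = 0.141 to 0.2 with an estimated correlation.

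Smooth muscle genes had a median of 2.14 in Axin2 against Negative, and pericyte genes 1.43; 0 of 16 in each list passed over all genes, and 13 smooth muscle genes and 1 pericyte gene rose adjusted over the list alone. BMP genes had a median of 1.06 (0 of 17, 5 adjusted over the list alone), Hedgehog genes 0.95 (0 of 11, 2 adjusted over the list alone) and heat shock genes 0.53 (0 of 13, 1 adjusted over the list alone). In the list test (camera) adjusted p was 1.23e-10 for smooth muscle, 1.8e-06 for pericyte, 0.00804 for BMP, 0.0126 for Hedgehog and 0.0445 for heat shock genes, and adjusted p = 0.141 to 0.369 with an estimated correlation. The Hedgehog call ended without Axin2 library 1 (adjusted p = 0.0746) or Negative library 0 (0.0976), and the heat shock call without Axin2 library 2 (0.215) or Negative library 0 (0.287). Without Negative library 0 the BMP and adventitial calls ended (0.0541 each).

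Markers of blood and epithelium were lower in Axin2 than in Negative cells. Hba-a1 and Hbb-bs fell by -8.11 ± 1.29 (limma, adjusted p = 0.0176) and -7.17 ± 1.14 (0.0176), and Alas2, a gene of heme synthesis at the lowest value in 1 Axin2 library, by -10.26 ± 1.65 (0.0182), 3 of 5 erythroid genes (5 adjusted over the list alone; median -8.11). Cldn18, Ager and Hopx fell by -3.1 ± 0.43 (0.00863), -2.75 ± 0.47 (0.021) and -2.94 ± 0.55 (0.0345), 3 of 18 epithelial genes (11 adjusted over the list alone; median -3.02). Endothelial and immune cell genes had medians of -1.21 and -2.52, with 0 of 15 and 0 of 19 past the threshold (4 and 1 fell adjusted over the list alone). Camera gave adjusted p of 4.71e-10 (erythroid), 1.75e-13 (epithelial), 1.58e-05 (endothelial) and 0.00055 (immune cell), and adjusted p = 0.141 to 0.329 with an estimated correlation. The immune cell call ended without Negative library 2 (adjusted p = 0.113).

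In the 14 lists that did not pass between Axin2 and Negative (camera, adjusted p = 0.113 to 0.909), Fgf1 fell by -2.84 ± 0.53 (limma, adjusted p = 0.0313), Vegfa by -2.8 ± 0.34 (0.00698), and Itga8 rose by 1.43 ± 0.26 (0.0271). Medians were 0.51 for canonical Wnt targets, 0.69 for Wnt ligands, 0.11 for alveolar fibroblast, 0.83 for mesothelial, -0.26 for Notch, 0.79 for chemokine, 1.07 for growth factor, 0.23 for retinoid, 1.5 for cell cycle, 0.17 for dissociation and 0.22 for interferon response genes. Median, mean and test direction differed in sign for FGF ligands (-0.88, 0.54, down), Schwann cell (-0.28, 0.95, up) and IL6 genes (-0.03, 0.01, up).

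Between Axin2 and Negative 85 genes passed (limma; 34 higher and 51 lower in Axin2; 2012 at unadjusted p < 0.05). The count was 33 without Axin2 library 1, 0 without Axin2 library 2 (limma; 1294 at unadjusted p < 0.05), 36 without either Pdgfra library, 585 without Negative library 0, 14 without Negative library 2, 49 without Wnt2 library 1 and 51 without Wnt2 library 2. The balance of directions was not stable: 3 higher and 30 lower without Axin2 library 1, 448 and 137 without Negative library 0, 7 and 7 without Negative library 2, and 12 and 66 with only these 2 groups fitted, where 33 of the 85 genes were shared. None of 34 named genes, Tlr4, Cldn18 and Vegfa included, held in all 10 fits. The calls that ended numbered 29 and 34 without Axin2 library 1 or 2, 3 and 32 without Negative library 0 or 2, 11 without either Axin2:Pdgfra library, 24 without either Pdgfra library, and 17 and 16 without Wnt2 library 1 or 2, with adjusted p up to 0.329. The differences with the Axin2 label, with and without Pdgfra, correlated at r = 0.16 across 14177 genes; 2 genes fell in both comparisons (0.02 from independent lists) and 0 rose in both. Of the 6 genes of the first comparison 83.3% had the same sign in the second, and of the 85 of the second 83.5% had it in the first.

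Wnt2 cells had less of many mural and adventitial transcripts, and more of some alveolar fibroblast transcripts, than the mean of the other 4 groups. Low pericyte levels were shared with the groups that carried Pdgfra. The library medians were -1.72 and -2.63 in Wnt2, -1.26 and -1.63 in Axin2:Pdgfra and -0.56 and -0.88 in Pdgfra. They were 2.7 and 2.98 in Axin2 and 2.08 and 1.15 in Negative. Low adventitial levels were not shared with the groups that carried Pdgfra (-1.38 and -2.22 in Wnt2, 2.15 in both Axin2:Pdgfra libraries, 0.75 and 0.86 in Pdgfra). Adventitial medians were 0.12 and -0.08 in Axin2 and -1.18 and -0.49 in Negative, where library 0 was near Wnt2 library 1. Alveolar fibroblast medians were 0.89 and 0.72 in Wnt2, 0.59 and 0.48 in Axin2:Pdgfra and 0.12 and 0.46 in Pdgfra. Those of Axin2 were -0.8 and -0.47 and those of Negative -0.87 and -0.5. Macf1 was at 18.99 ± 0.38 (mean ± SD, n = 2), against 17.72 in all 4 libraries with the Pdgfra label of the other line, and rose by 2.16 ± 0.14 (log2 ± SE; limma, adjusted p = 2.24e-06). Because the distributions are near-identical, the equal values of 17.72 can mark a shared rank rather than equal measured levels. The size and adjusted p of the Macf1 rise thus depend partly on the gaps between the top values. Itga8 and Limch1 rose by 1.89 ± 0.21 (0.000252) and 1.44 ± 0.2 (0.00172), so that 3 of 19 alveolar fibroblast genes passed (10 adjusted over the list alone; median 0.96). Pdgfrb fell by -3.37 ± 0.24 (5.34e-06), among 11 of 16 pericyte genes (15 adjusted over the list alone; median -2.54). Acta2 fell by -3.88 ± 0.52 (0.00141) and Myl9, a myosin light chain, by -4.14 ± 0.42 (0.000174), among 9 of 16 smooth muscle genes (1 up and 10 down adjusted over the list alone; median -2.44). Cd248, Pi16 and Dcn fell by -7.81 ± 0.74 (8.88e-05), -6.35 ± 1.03 (0.00507) and -4.03 ± 0.42 (0.000188), among 11 of 19 adventitial genes (13 adjusted over the list alone; median -2.25). The camera test gave adjusted p of 2.79e-08 for alveolar fibroblast, 1.66e-19 for pericyte, 2.32e-11 for smooth muscle and 2.81e-15 for adventitial genes (adjusted p = 0.0761, 0.0547, 0.0806 and 0.0614 with an estimated correlation).

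Signalling genes of several pathways were lower in Wnt2 cells than in the mean of the other 4 groups. Some of these lists were about as low in another group. Hedgehog library medians were -0.42 and -0.71 in Wnt2 and -0.91 and -1.35 in Negative. Notch medians were -0.89 and -0.3 in Wnt2 and -1.01 and -0.85 in Axin2:Pdgfra. Canonical Wnt target medians were -0.59 and -0.66 in Wnt2 and 0.11 and -0.71 in Negative. Wnt5a fell by -1.96 ± 0.46 (limma, adjusted p = 0.0412), alone among 16 Wnt ligands and modulators (4 adjusted over the list alone; median -1.25), and Lgr6, at the lowest value in 1 Negative library, by -6.22 ± 1.37 (0.028), alone among 16 canonical Wnt targets in either adjustment (median -0.97). Notch3 and Nrarp fell by -3.71 ± 0.44 (0.000539) and -5.22 ± 0.8 (0.00325), 2 of 14 Notch genes in either adjustment (median -0.92). Cxcl1 and Ccl11 fell by -1.87 ± 0.4 (0.0241) and -4.72 ± 1.02 (0.0258), 2 of 16 chemokine genes in either adjustment (median -0.84). With a library left out, the calls of Wnt5a, Lgr6 and Ccl11 ended in most fits, and those of Nrarp and Cxcl1 in at least 1. The differences then ranged from -2.46 to -1.47 for Wnt5a, -7 to -5.44 for Lgr6 and -5.9 to -3.54 for Ccl11. None of 11 Hedgehog genes passed over all genes (4 fell adjusted over the list alone; median -0.89). Adjusted p by camera was 0.000297 for Wnt ligands, 0.0105 for canonical Wnt targets, 0.000278 for Notch, 0.000703 for chemokine and 0.00355 for Hedgehog genes, and adjusted p = 0.0806 to 0.204 with an estimated correlation. Without Wnt2 library 2 the calls for canonical Wnt targets (adjusted p = 0.114), Hedgehog (0.0737) and chemokine genes (0.147) ended.

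Several lists of other cell types were lower in Wnt2 libraries, though not the immune cell list (median 0.21). Some were about as low in a group with the Pdgfra label. The epithelial library medians were -1.18 and -1.33 in Axin2:Pdgfra and -1.79 and -0.5 in Wnt2. The Schwann cell medians were -2.87 and -2.51 in Pdgfra and -2.36 and -2.51 in Wnt2. Mesothelial Upk1b fell by -5.94 ± 0.55 (limma, adjusted p = 8.01e-05), 1 of 9 (6 adjusted over the list alone; median -4.57). Scgb1a1, a club cell secretory protein, and Ager fell by -2.28 ± 0.29 (0.00105) and -2.02 ± 0.37 (0.0106), among 5 of 18 epithelial genes (7 adjusted over the list alone; median -1.16). Eng fell by -1.73 ± 0.29 (0.00597), 1 of 15 endothelial genes in either adjustment (median -0.61). None of 7 Schwann cell, 5 erythroid or 21 dissociation genes passed over all genes (2 dissociation genes fell adjusted over the list alone; medians -2.56, -1.87 and -0.28). Camera gave adjusted p of 1.41e-07 (mesothelial), 4.92e-08 (epithelial), 0.00355 (endothelial), 0.00728 (Schwann cell), 0.0233 (erythroid) and 0.0105 (dissociation), and adjusted p = 0.0547 to 0.377 with an estimated correlation. The erythroid call ended without Negative library 0 (adjusted p = 0.0592) or Wnt2 library 2 (0.706, mean 0.5), and the dissociation call without Wnt2 library 1 (0.772, mean 0.04).

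In the 12 lists that did not pass (camera, adjusted p = 0.051 to 0.885), genes moved both ways in Wnt2 cells. Lox and Mfap4 rose by 1.64 ± 0.34 (limma, adjusted p = 0.0208) and 1.37 ± 0.21 (0.00374), Angpt1 by 1.95 ± 0.41 (0.0226), Vegfd by 1.71 ± 0.27 (0.00447) and Bmp3 by 1.7 ± 0.32 (0.0125). Loxl2 fell by -1.62 ± 0.3 (0.0124), Postn by -2.05 ± 0.32 (0.00374), Igf2 by -4.68 ± 0.69 (0.00262), Fgf18 by -4.33 ± 0.98 (0.0319) and Ltbp2 by -3.42 ± 0.35 (0.000174). The call of Fgf18 ended in most fits with a library left out, where its difference ranged from -6.12 to -2.54. Among 19 elastic fibre genes 3 rose and 5 fell (4 and 6 adjusted over the list alone; median -0.43). Medians were 1.26 for FGF, -0.28 for TGF-beta, -0.37 for collagen, -1.19 for growth factor, -0.02 for retinoid, -0.34 for cell cycle and -0.45 for interferon response genes. Median, mean and test direction differed in sign for BMP (-0.1, -0.69, up), IL6 (0, -0.23, up) and heat shock genes (0, -0.06, down).

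In Wnt2 against the other 4 lineages 306 genes passed (limma; 102 higher and 204 lower; 2035 at unadjusted p < 0.05). Gria1 and Gria3, glutamate receptor subunits, rose by 2.66 ± 0.51 (adjusted p = 0.014) and 3.08 ± 0.39 (0.00105), and Cwc22, a splicing factor with near-identical copies, by 4.15 ± 0.89 (0.0253). The count was 185 without Axin2 library 2, 190 without Pdgfra library 1, 203 without Pdgfra library 2, 63 without Wnt2 library 1 (11 higher and 52 lower) and 66 without Wnt2 library 2 (13 and 53). With library weights the excess of lower genes was not kept (655 higher and 667 lower). Of 55 named genes 18 held in all 10 fits, Macf1, Itga8, Fat3, Cd248, Olfml2b, Actg2, Myl9, Acta2, Dcn, Col14a1, Pdgfrb, Notch3, Upk1b and Pdgfra among them. The calls that ended numbered 30 and 32 without Wnt2 library 1 or 2 (adjusted p up to 0.798), 11 without either Pdgfra library, 9 without either Axin2 library, and 6 and 4 without Axin2:Pdgfra library 1 or 2. Line, reporter and lineage were not separable in this comparison.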

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

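The interaction was tested for every list by a test fixed before the values were seen, and the 3 lists here are those that passed it. Pericyte and smooth muscle genes drew attention because their fall with the Pdgfra label was larger among cells with the Axin2 label (medians -4.36 and -2.55) than among cells without it (-2.54 and -1.13), interaction medians of -2.05 and -1.68 (camera, adjusted p = 1.42e-08 and 1.43e-06). Erythroid genes, Hba-a1 and Hbb-bs among them, had medians of 1.12 and -6.18 in the same comparisons and an interaction median of 7.59 (camera, adjusted p = 1.14e-06). Their library medians were 5.72 and 5.57 in Negative and -3.53 to 0.88 in all other libraries. The erythroid interaction thus came from high levels in the Negative group alone. With an estimated correlation the adjusted p was 0.483 for each of the 3 lists, and fry gave adjusted p of 0.142 for pericyte, 0.286 for smooth muscle and 0.21 for erythroid genes.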

How the results depend on the processing

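The filter at 8, values under 6 raised to 6, library weights, the length trend removed and both omissions of 2 libraries were chosen after the data were seen; the other settings were fixed before. Of 219 calls of named genes 0 reversed in any setting; those kept were 215 with no filter, 45 without trend or robust, 95 of 164 with only the compared groups, 98 at an adjusted p under 0.01, 48 with treat, 174 with the replicate block, 177 with the second index block, 209 with the filter at 8, 198 with low values raised, 162 with library weights, 206 with the length trend removed, and 117 to 195 with a library left out. Of 76 camera calls of lists 0 were kept with an estimated correlation, 45 with fry, 68 with the replicate block and 66 to 75 with a library left out. Counts are given below for all 5 lineages, then for Axin2:Pdgfra against Axin2, Axin2:Pdgfra against Pdgfra, Axin2 against Negative, Pdgfra against Negative and Wnt2 against the other 4 (1163, 326, 6, 85, 412 and 306 in the report), and for genes enriched in Axin2, Pdgfra, Negative and Wnt2 (1, 1, 23 and 1). Limma without trend or robust gave 205, 95, 0, 0, 71 and 66, and 0 enriched genes in each of the 4 lineages; at unadjusted p < 0.05 the zeros were 1730 and 1692, and 87, 39, 187 and 38. With only the compared groups fitted, Axin2:Pdgfra against Axin2 gave 156, Axin2:Pdgfra against Pdgfra 2, and the enriched genes were 8 for Axin2, 47 for Negative and 0 for Wnt2 (limma; 148 at unadjusted p < 0.05). An adjusted p under 0.01 gave 407, 107, 3, 9, 133 and 103, with 0 enriched genes for Axin2 and 5 for Negative, and the stricter threshold by construction can only lower counts. Treat (limma) gave 61 for Axin2:Pdgfra against Axin2, 1 for Axin2:Pdgfra against Pdgfra, 0 for Axin2 against Negative (828 at unadjusted p < 0.05), 29 for Pdgfra against Negative, 40 for Wnt2, and 0 enriched genes in each of the 4 lineages. The replicate block gave 41 for Axin2:Pdgfra against Pdgfra, 396 for Axin2 against Negative (300 higher and 96 lower, against 34 and 51), a split of 331 and 45 for Pdgfra against Negative, and 16, 12 and 2 genes enriched in Axin2, Negative and Wnt2, and since Negative 0 is the only library numbered 0, this block in effect also leaves it out (448 higher and 137 lower for Axin2 against Negative without it), while same-numbered libraries of different groups had residual correlations of only -0.06 to 0.03 over 6 group pairs. The second index block gave 11 and 26 for those comparisons and 15 genes enriched in Negative. The filter at 8 gave 14 for Axin2:Pdgfra against Pdgfra, 2 genes enriched in Axin2 and 2 in Wnt2, and correlations of 0.35 for the Pdgfra and 0.2 for the Axin2 differences. Raising values under 6 gave 3 genes enriched in Axin2, 2 in Pdgfra and 45 in Negative, and split the Wnt2 genes into 121 higher and 158 lower (43.4% higher, against 33.3%). Library weights (2.18 for Wnt2, 0.58 for Negative) gave 22 for Axin2 against Negative, 199 for Pdgfra against Negative, 1322 for Wnt2 (655 higher and 667 lower), and 9 and 6 genes enriched in Negative and Wnt2. With the length trend removed, Axin2:Pdgfra against Pdgfra gave 10 (1 higher and 9 lower), 4 of the 6 genes among them, and the gene enriched in Pdgfra was no longer Neat1; the Spearman correlation of this difference with length was -0.22 before and -0.02 after, the largest of the comparisons (0.13 for Wnt2). Without Negative 2 and Wnt2 2 the counts were 532 for all 5 lineages, 2 for Axin2:Pdgfra against Pdgfra, 0 for Axin2 against Negative (limma; 1339 at unadjusted p < 0.05), 210 for Pdgfra against Negative, 122 for Wnt2, and 0 genes enriched in Axin2, Pdgfra or Negative. Without Negative 2 and Axin2:Pdgfra 2 they were 38 for Axin2:Pdgfra against Pdgfra, 11 for Axin2 against Negative, 481 for Wnt2, and 0 and 3 genes enriched in Axin2 and Negative. With 1 library left out, where the lone library of a group is assumed to vary like the other groups, the ranges were 592 to 1534 for all 5 lineages, 35 to 473, 0 to 57, 0 to 585, 82 to 633 and 63 to 439 for the 5 comparisons, 0 to 42 for the interaction, 0 to 18, 0 to 1, 0 to 28 and 0 to 4 for the enriched genes, and correlations of 0.21 to 0.3 for the Pdgfra and 0.12 to 0.17 for the Axin2 differences. Differences that reversed, none past the threshold except 2 lists, were those of Pdgfra in Axin2 against Negative (0.58; -0.06 with the replicate block; -0.09 to 1.24 with a library left out) and in the interaction (-0.3; 0.34 with the replicate block; 0.1 with the length trend removed; -0.97 to 0.37), of Wnt2 in Pdgfra against Negative (-0.42; 0.11 in each omission of 2 libraries; -1.74 to 0.91), in Axin2:Pdgfra against Axin2 (0.31; -0.15 to 0.77), in the interaction (0.72; -0.6 to 2.05) and in Wnt2 cells (0.15; -0.18 to 0.48), of Axin2 in Axin2:Pdgfra against Axin2 (-0.23; 1.02 without Negative 2 and Axin2:Pdgfra 2; -1.48 to 1.02), in the interaction (-0.59; 0.96 in the same setting; -1.84 to 0.66) and in Axin2:Pdgfra against Pdgfra (0.07; -1.18 to 1.32), and the means of the erythroid (-1.95; -4.4 to 0.5) and dissociation lists in Wnt2 (-0.33; -0.71 to 0.04). Apart from fewer libraries or a stricter threshold, the cause was not tested. Normalization by RLE, upper quartile or library size, filters on counts or CPM, pseudocounts, DESeq2 and limma-voom were not run because the files hold log2 values, and what depth limits could not be measured.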

Other observations

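Of the tests in this part, those of the sex chromosomes and of the mouse line were written before the results were seen and all others after. In the Negative libraries, transcripts of alveolar type 1 cells, the flat cells of gas exchange, exceeded the other groups by more than those of type 2 cells, which make surfactant. Of 20 type 1 markers, 9 were among the 23 genes enriched in Negative, and of 13 type 2 markers 0. The markers were listed after those 23 genes had been seen, so this overlap is descriptive and no test. Ager was at 15.54 in Negative and 12.04 in the mean of the other groups, Lama3 at 15.01 and 10.91, and Sftpc, a surfactant protein, at 14.99 and 13.88 (log2, means of 2 and 8 libraries).

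Type 1 markers outside the 23 genes were higher in Negative by a median of 4.25, as type 1 cells in the gate, or RNA released from them, would give. Epithelial cells of every kind alike, or simply fewer mesenchymal cells, would raise both kinds of marker alike if their levels elsewhere were alike. Both were higher. Among genes under 11 elsewhere the type 2 medians were 1.34 in Negative library 0 and 1.46 in library 2. The type 1 medians were 4.69 and 3.94, larger by 3.35 and 2.48. Most type 2 genes of that set were at a higher level elsewhere (Chil1 10.96, Lpcat1 10.9) than type 1 genes such as Igfbp2 (7.99) and Aqp5 (8.19). A higher level elsewhere shrinks a log2 difference, so the gap excludes neither explanation. Napsa and Sftpd, type 2 genes low elsewhere (8.02 and 8.52), were higher by 2.2 and 2.19. A deviating Negative library does not account for the higher type 1 markers, since the lower of the 2 libraries exceeded the highest of the 8 others by 2.3. No test here could separate sorted type 1 cells from released RNA, and no biological explanation was tested.

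Length was weighed for the genes changed in Wnt2 libraries, whose median transcript lengths were 6.05 kb for the higher, 3.87 kb for the lower and 3.29 kb for all tested genes; called genes were longer than tested genes in the other comparisons too (medians of 4.27 to 5.98 kb). After a length trend was removed from each library, 95.1% of the lower calls were kept, which argues against length as their source, and 75.5% of the higher calls (77 of 102; median log2 from 1.63 to 1.52), which leaves it open for the rest. Sex stays open: the share of X and Y genes among the calls was 1.09 times that among other tested genes (11 of 304, 3.62% and 3.32%), but Xist differed between the 2 Wnt2 libraries (17.04 and 7.81), so sex-linked genes varied within the group and a low share excludes nothing. For mouse line and reporter, 0 Wnt2 libraries came from the line of the other 4 groups, so they and the lineage itself, the biological explanation, could not be told apart.

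The Axin2 and Wnt2 transcripts did not pass the threshold with their label, though with 2 libraries per group a difference is not excluded, and swapped labels were weighed. A single swapped Wnt2 library is not supported, since the 2 Wnt2 libraries correlated more closely with each other than with any other, by 0.043. For an exchange of single libraries across the Axin2 label within an EGFP gate, 0 of 2 gates had a library out of place on both sides. That result could not decide. Negative library 2 and Axin2:Pdgfra library 2 correlated at no more than 0.778 and 0.816 with any library. A true partner of either under the wrong label need not have been nearer to it. Nor could these tests detect an exchange of both libraries of a group. Negative library 0 and Axin2:Pdgfra library 1 were each nearer to a library across the Axin2 label (Spearman 0.828 and 0.852) than to their partners (0.778 and 0.816), the libraries with most genes at the lowest value. Pdgfra library 2 was nearer to Wnt2 libraries 2 and 1 (0.885 and 0.884) than to its partner (0.857). Whether a single Axin2 label was wrong could not be decided from marker medians. Over type 1 genes the lower Negative median exceeded the higher Axin2 median by 2.3. Over adventitial genes the lower Axin2:Pdgfra median exceeded the higher Pdgfra median by 1.29. Each gap was more than the range within a group. Both gene sets were picked for this after such a difference between these groups had been seen, so the gaps do not exclude a wrong label. The biological explanation, that an inherited label outlasts the transcript of its driver gene, was not tested.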
